A study of Homo sapiens with 9 samples.

How the data were processed

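KGN is a human granulosa cell tumour line that is widely used as a model of ovarian granulosa cells. Per the labels' protocols, cells were fasted for 12 h and then treated for 72 h with solvent, with 0.5 µg/ml insulin or with 1 µg/ml insulin. Total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal RNA-seq kit, per the labels' protocols. The 9 libraries form 3 groups of 3, called here control, the lower dose and the higher dose, and each library is named by its group and the replicate number of its title. The labels do not say that replicates of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

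The authors deposited a table of raw read counts per gene symbol and a table of FPKM values for the same genes and libraries. Trimmomatic, HTSeq and DESeq are named without versions, with the genome build hg38, per the submitters' processing notes; the role of each tool, the aligner, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The deposited counts are whole numbers and were used as they stand. The deposited FPKM values are the same counts rescaled: over 11053 genes with at least 50 counts in every library, the gene length implied by the ratio of the 2 tables was a whole number within 1e-6 for all 11053. FPKM therefore holds no measurement beyond the counts and was used only for an alternative analysis.

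The count table holds 15983 genes, of which 15547 (97.3%) have a symbol in GENCODE release 29, the annotation used here for positions on hg38. Library totals ran from 18965722 to 20446405 counts. A count of 0 at the smallest total allows up to 3 counts, or 0.158 CPM. Such limits cover counting error only. No transcript encoded in mitochondrial DNA was analysed here, since none of the 28 listed symbols matched a row. Replicates were compared before they were averaged: the chi-square statistic per degree of freedom between libraries of a group ran from 2.18 to 8.38 over 9 pairs, so each library was counted as a sample of its own.

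Genes were filtered with filterByExpr in edgeR 4.0.16 at its default settings (minimum count 10, minimum total 15), which left 12665 genes and removed 3318. Counts were scaled by TMM and fitted in one model over all 9 libraries, so that the 3 groups share an estimate of the spread. The edgeR quasi-likelihood F-test gave each comparison, with Benjamini-Hochberg adjustment over all tested genes, and a gene was called at an adjusted p under 0.05. Standard errors are the absolute log2 fold change divided by the square root of F, and 95% intervals use the t distribution at the fitted degrees of freedom. All p-values from these models are two-sided. The common biological coefficient of variation was 5.39%.

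For 34 gene lists, camera in limma 3.58.1 was run with a preset correlation of 0.01 between genes on log2 CPM with a prior count of 2, for every list with at least 5 tested members (30 lists), with Benjamini-Hochberg adjustment over the lists. Each list was also tested with a correlation estimated from the residuals and with fry, which asks whether the genes of a list move, on balance, in one direction. A list's score in a library is the mean of its members' log2 CPM after each gene's mean was removed. An exact permutation test over the 280 partitions of the 9 libraries into 3 groups of 3, chosen after seeing the data, was added for these scores. The groups, tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined. The rule names up to 6 called genes per direction against control (5 between doses) with at least 2 CPM and no overlap between groups, the 3 genes of smallest p where no gene is called, up to 2 members of smallest p in each called list (at most 8 lists) and up to 5 called members of other lists, for the comparisons with control, and INSR, IGF1R, IRS1 and IRS2 everywhere.

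The pipeline was tested on simulated counts drawn from the real means and library sizes of 12665 genes, with 200 genes changed in each of 3 runs. For the lower dose against control, edgeR recovered 52.7% of 1.25-fold, 81.6% of 1.5-fold and 93.9% of 2-fold changes. For the higher dose against control these shares were 56.7%, 78.1% and 92.9%, and between the doses they were 54.2%, 87.6% and 91.9%. In 5 runs of the list tests, camera with the preset correlation called 2 of 450 unchanged lists, and a list of 24 members shifted by 10% was called in 5 of 5 runs by each of the 3 list tests. Genes were drawn independently of each other, so these list results do not carry over to real lists whose members vary together, where variance inflation reached 24.2.

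Alternatives were DESeq2 1.42.0 without the count filter (15981 genes with a p-value), RLE size factors, no count filter, a stricter filter of 1 CPM in 3 libraries, models of the 2 compared groups alone, the replicate number as a block, the older quasi-likelihood method, a minimum log2 fold change of 1, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a filter of 1 FPKM in 3 libraries, limma on log2(FPKM + 1) without that filter, and leaving out each library in turn. No TMM scaling was added after seeing the data. Near-identical gene copies were found by aligning the longest protein-coding transcript of each gene to all GENCODE 29 transcripts with minimap2 2.31-r1302, and a gene was counted as having such a copy where at least 50% of that transcript aligned at 99% identity or more to another gene. R 4.3.3 was used throughout.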

Results

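RNA sequencing measured gene expression in KGN cells after 72 h with solvent (3 libraries), 0.5 µg/ml insulin (3 libraries) or 1 µg/ml insulin (3 libraries). Library totals ran from 18965722 to 20446405 counts in control, from 19508466 to 20422534 at the lower dose and from 19887010 to 20208576 at the higher dose. The 10 most abundant genes took between 5.57% and 5.84% of the counts of a library. The study's title and design text give the question as the response of granulosa cells to high insulin.

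The cells expressed the machinery that receives insulin. Over the 9 libraries INSR, the insulin receptor, was measured at 14.4 ± 1.21 CPM, IGF1R, the receptor for insulin-like growth factor 1, at 66.6 ± 3.80 CPM, and the receptor substrates IRS1 and IRS2 at 18.1 ± 1.11 and 45.5 ± 4.58 CPM (SD, n = 9). The granulosa transcription factor FOXL2 was measured at 26.2 ± 2.02 CPM, the FSH receptor gene FSHR at 18.1 ± 2.43 CPM, AMH at 12.5 ± 1.33 CPM and CYP19A1, which encodes aromatase, at 8.31 ± 1.06 CPM (SD, n = 9). STAR, which moves cholesterol into mitochondria for steroid synthesis, stood at 28.3 ± 3.50 CPM, and CYP11A1, the side-chain cleavage enzyme, at 6.51 ± 0.759 CPM (SD, n = 9). Other members of the granulosa and steroid lists were scarce. Of the granulosa markers 20 of 23 were tested, and of the steroid synthesis genes 19 of 26. INHA stood at 0.656 ± 0.266 CPM, HSD17B1 at 0.730 ± 0.153 and NR5A2 at 0.878 ± 0.226 (SD, n = 9). The filter removed AMHR2, ESR2, HSD3B1 and HSD3B2, with 34, 31, 10 and 41 counts over all libraries. CYP17A1, the androgen-forming enzyme of theca cells, had 1 count over all libraries, IGF1 had 2 and IGF2 had 3. Collagen and other matrix genes were the most abundant among the listed genes: COL1A1 reached 9027 ± 589 CPM, FN1 6155 ± 204 CPM and SPARC 5558 ± 91.8 CPM (SD, n = 9). Markers listed for other cells ranged widely. Of those for fibroblasts and smooth muscle 10 of 12 were tested, among them ACTA2 at 405 ± 43.4 CPM and THY1 at 238 ± 11.4 CPM, and of the epithelial markers 9 of 15, among them KRT7 at 21.6 ± 2.19 CPM (SD, n = 9). Of 18 blood and immune markers 3 were tested, among them CD68 at 58.1 ± 3.60 and CD74 at 57.9 ± 7.78 CPM, and of 10 endothelial markers 2, among them KDR at 18.3 ± 1.29 CPM (SD, n = 9). EPCAM had 7 counts over all libraries, PECAM1 53 and HBB 1. Apart from the 4 receptor and substrate genes, the genes in this paragraph were chosen after their values were seen.

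No group difference stood out in the whole profile. Of the variance of log2 CPM, 25.6% lay between the 3 groups, where random groups are expected to hold 25%, and 94 of the 280 partitions of the libraries gave as large a share (exact permutation p = 0.336). The first principal component held 18.1% of the variance and the second 15.9%. On the first, control 3 (15.4) and lower dose 1 (-12.3) lay at the ends, and on the second lower dose 1 (-15.2) was the lowest, with lower dose 2 and 3 at 11.7 and 7.41. The chi-square statistic per degree of freedom between lower dose 1 and the other libraries of its dose was 7.93 and 8.38, against 2.18 between those 2. The 3-group edgeR quasi-likelihood test called 0 of 12665 genes, with 567 (4.48%) at an unadjusted p under 0.05, and DESeq2 called 1, LOC102724200. The smallest Benjamini-Hochberg adjusted p from edgeR was 0.387, for that same gene, an annotated protein-coding locus on chromosome 21 from 5155774 to 5165464 in the RefSeq annotation of the same human assembly.

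Of the receptor and substrate genes, INSR, IGF1R and IRS1 differed little between groups, and IRS2 stood lower at the higher dose, as the plot of their fold changes shows. At the lower dose, the log2 fold change against control was 0.12 ± 0.10 for INSR, -0.04 ± 0.06 for IGF1R, 0.07 ± 0.09 for IRS1 and 0.06 ± 0.07 for IRS2 (SE). At the higher dose it was 0.05 ± 0.10 for INSR, -0.09 ± 0.06 for IGF1R, 0.09 ± 0.09 for IRS1 and -0.19 ± 0.07 for IRS2 (SE). Their 95% intervals in both comparisons lay between 0.787-fold (IRS2, higher dose) and 1.26-fold (INSR, lower dose). Only that of IRS2 at the higher dose, 0.787- to 0.976-fold, excluded no change (edgeR quasi-likelihood, unadjusted p = 0.0184). It did not pass after adjustment over all genes.

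**Figure D1:**
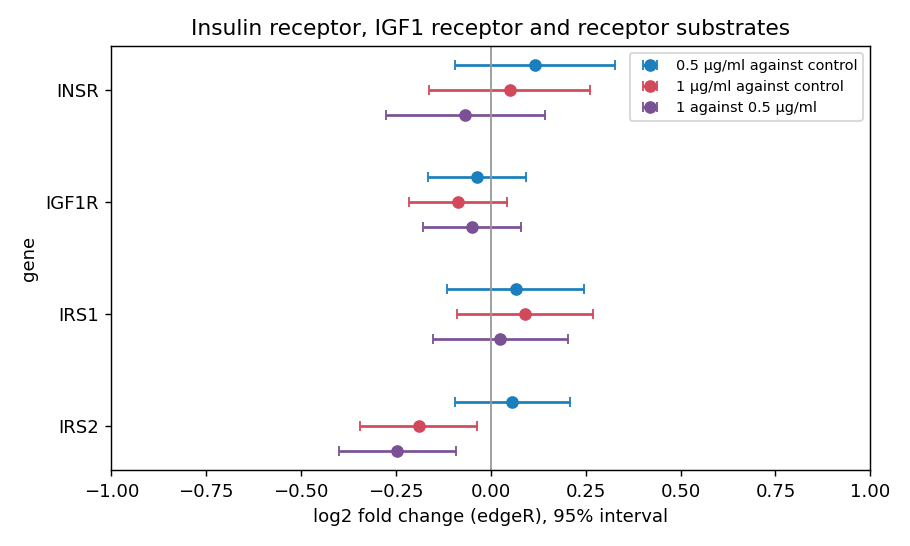
Log2 fold changes (horizontal axis, edgeR) of INSR, IGF1R, IRS1 and IRS2 (vertical axis) in the 3 comparisons, with points for the estimates and bars for 95% intervals. Estimates run from -0.25 (IRS2, between the doses) to 0.12 (INSR, lower dose against control), and none passed the test after adjustment over all genes.

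The comparison of 0.5 µg/ml insulin with control asks what the lower dose does to the cells. JUNB, an AP-1 transcription factor of the immediate early class (chromosome 19, 12791496 to 12793315, hg38), was measured at 55.1 ± 1.73 CPM with insulin and 47.2 ± 1.52 CPM in control (SD, n = 3 each). Its log2 fold change of 0.22 ± 0.06 (SE) held in all 3 libraries against all 3 controls, and its adjusted p was 0.765 over all genes (edgeR quasi-likelihood, Benjamini-Hochberg) and 0.0303 adjusted over the list alone, which has 27 tested immediate early genes. It was the only call adjusted over the list alone in this comparison. That adjustment covers the 27 genes of the list, and not the number of lists and comparisons examined. FOSL1, another AP-1 member, had a log2 fold change of 0.18 ± 0.06 (SE) with an adjusted p of 0.765 from the same test.

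Across all genes, the edgeR quasi-likelihood test called 0 higher and 0 lower at the lower dose, with 776 of 12665 genes (6.13%) at an unadjusted p under 0.05, and DESeq2, run without the count filter, called 0 of 15981 with 573 at an unadjusted p under 0.05. The smallest adjusted p was 0.525 (edgeR, Benjamini-Hochberg). The 95% interval lay within 1.5-fold either way for 87.7% of the tested genes and within 2-fold for 95.2%. Groups did not overlap for 1357 genes (10.7%), where chance gives 10%. The smallest p values belonged to LOC102724200 (0.387 ± 0.233 CPM against 1.83 ± 0.778 in control), TMED7, a cargo receptor of the secretory pathway (62.4 ± 2.36 against 76.0 ± 4.80 CPM), and BOLA2B (0.186 ± 0.109 against 1.56 ± 1.42 CPM; SD, n = 3 each). BOLA2B has a near-identical copy, BOLA2, and TMED7 shares 24.9% of its transcript with a read-through gene, so their counts are uncertain. LOC102724200 has no GENCODE transcript to align, so whether it has a copy was not examined. Without control 2 the test called 1 gene lower, LOC102724200.

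Of the 30 gene lists tested, camera with a preset correlation called 6 at the lower dose, all upward, and each call was lost with an estimated correlation, where the smallest adjusted p over the 30 lists was 0.883. Interferon response genes had the smallest p: 23 of 27 members lay above 0, with a median log2 fold change of 0.10 (camera adjusted p = 0.000151; adjusted p = 0.883 with an estimated correlation). IFI6, an interferon-induced mitochondrial protein, was measured at 1303 ± 82.7 against 1180 ± 60.3 CPM, and the chemokine CXCL10 at 1.22 ± 0.137 against 0.652 ± 0.534 CPM (SD, n = 3 each). Ribosomal protein genes had 31 of 41 members above 0 and a median of 0.05 (camera adjusted p = 0.000605; adjusted p = 0.883 with an estimated correlation), among them RPS15 (log2 fold change 0.13 ± 0.04, SE) and RPS16 (0.14 ± 0.05, SE). The ATF4 targets of the amino acid response had 23 of 26 members above 0 and a median of 0.07 (camera adjusted p = 0.000775; adjusted p = 0.883 with an estimated correlation). SLC38A2, an amino acid transporter and an ATF4 target, went the other way at -0.11 ± 0.05 (SE). CBS, of the transsulfuration pathway, stood at 15.1 ± 6.12 against 10.98 ± 0.869 CPM (SD, n = 3 each); its count was 431 in lower dose 2 and between 223 and 243 in the other libraries of that dose, and 96.5% of its transcript has a near-identical copy, CBSL. Immediate early genes had a median of 0.06 with 20 of 27 above 0 (camera adjusted p = 0.0105; adjusted p = 0.883 with an estimated correlation). Mitosis genes had a median of 0.05 with 20 of 26 above 0 (camera adjusted p = 0.0355; adjusted p = 0.883 with an estimated correlation), BUB1 and TTK, both mitotic checkpoint kinases, at 0.12 ± 0.06 and 0.12 ± 0.07 (SE). The mitosis call was lost without control 3, lower dose 2 or lower dose 3, with medians of 0.000193 (where the test pointed down), 0.03 and 0.04. DNA replication and S phase genes had a median of 0.07 with 22 of 26 above 0 (camera adjusted p = 0.0434; adjusted p = 0.883 with an estimated correlation), CHAF1B, a chromatin assembly factor, at 0.22 ± 0.11 and PCNA, the sliding clamp of DNA polymerase, at 0.11 ± 0.06 (SE). The S phase call was lost without control 2 (median 0.03) or control 3 (0.00902), and without lower dose 1, where the median turned to -0.0255. The 9 tested epithelial markers, whose scores went with those of S phase genes across the libraries (Pearson r = 0.932, exact permutation p = 7.16e-05, adjusted p = 0.0270, chosen after the data were seen), had a median of 0.10 at this dose with 5 above 0 and were not called (camera adjusted p = 0.288). Scores of both lists were highest in library 1 of each group. The calls of the other 4 lists were lost when a library was left out: interferon response without control 3 (median 0.02) or lower dose 2 (0.04), and ribosomal proteins without control 2 (0.01) or lower dose 3 (-0.000354). ATF4 targets lost theirs without control 3 (0.03) or lower dose 2 (0.06), and immediate early genes without control 1 (0.06), control 3 (0.05) or lower dose 2 (0.07). The fry test called 0 lists, with a smallest adjusted p of 0.908. Camera's count was 1 without control 3, 2 without lower dose 2 and 12 without lower dose 1.

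The other 24 lists were not called at the lower dose, with median log2 fold changes from -0.05 (fatty acid synthesis and desaturation) to 0.11 (replication-dependent histones, 6 members). Lipid breakdown, FOXO targets, granulosa cell markers and heat shock chaperones had medians whose sign differed from that of their mean or test. Steroid hormone synthesis had a median of -0.05 over 19 tested members, cholesterol synthesis and uptake -0.03 over 24, and glycolysis 0.02 over 21. For all 24 cholesterol genes and all 21 glycolysis genes the 95% interval excluded a 1.5-fold change.

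The comparison of 1 µg/ml insulin with control asks what the higher dose does. IPMK, an inositol phosphate kinase (chromosome 10, 58191517 to 58267934, hg38), was measured at 6.24 ± 0.448 CPM with insulin and 9.02 ± 1.08 CPM in control (SD, n = 3 each), and POLR2J, an RNA polymerase II subunit, at 24.7 ± 2.36 against 19.6 ± 0.897 CPM. Both groups of values were free of overlap, and both genes had an adjusted p of 1.00 (edgeR quasi-likelihood, Benjamini-Hochberg), with log2 fold changes of -0.53 ± 0.12 and 0.33 ± 0.08 (SE). POLR2J shares 37.0% of its transcript with POLR2J3. LOC102724200 was again among the 3 genes of smallest p, at 0.463 ± 0.103 against 1.83 ± 0.778 CPM (SD, n = 3 each).

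At the higher dose the edgeR quasi-likelihood test called 0 genes higher and 0 lower, with 299 of 12665 (2.36%) at an unadjusted p under 0.05, and DESeq2 called 0 of 15981 with 173 at an unadjusted p under 0.05. The 95% interval lay within 1.5-fold for 88.3% of the tested genes and within 2-fold for 95.4%. Groups did not overlap for 979 genes (7.73%), where chance gives 10%.

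Camera with a preset correlation called 10 lists at the higher dose, 4 upward and 6 downward, and each call was lost with an estimated correlation, where the smallest adjusted p over the 30 lists was 0.767. Upward, DNA replication and S phase genes had 23 of 26 members above 0 and a median of 0.06, with MCM6 and MCM7, subunits of the replicative helicase, at 0.19 ± 0.07 and 0.14 ± 0.08 (SE). Cholesterol synthesis and uptake had 20 of 24 above 0 and a median of 0.05, with ACAT2, which makes acetoacetyl-CoA, at 0.13 ± 0.06 and FDFT1, squalene synthase, at 0.11 ± 0.06 (SE); 69.7% of the ACAT2 transcript matches an overlapping transcript, SOD2-OT1. Ribosomal protein genes had 35 of 41 above 0 and a median of 0.03, RPS15 at 0.12 ± 0.04 and RPS16 at 0.11 ± 0.05 (SE). The nuclear-encoded respiratory chain had 27 of 35 above 0 and a median of 0.03, with NDUFA2, a complex I subunit, at 0.17 ± 0.08 and CYCS, cytochrome c, at -0.08 ± 0.06 (SE). Camera gave the first 3 of these an adjusted p of 0.000517 each and the respiratory chain 0.0288, and with an estimated correlation the adjusted p was 0.767 for all 4. The S phase call was lost without control 2 (median 0.03), control 3 (0.01) or higher dose 1 (-0.01), that of cholesterol synthesis without control 1 (0.01) and that of ribosomal proteins without control 2 (0.01) or higher dose 3 (0.01). The respiratory chain lost its call without control 2 (0.01), control 3 (0.03), higher dose 2 (0.02) or higher dose 3 (0.02).

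Downward, extracellular matrix genes had 25 of 31 members below 0 and a median of -0.04. COL5A1, a fibrillar collagen chain, was measured at 1251 ± 38.6 against 1341 ± 19.3 CPM and FBN1, fibrillin, at 1639 ± 41.7 against 1760 ± 118 CPM (SD, n = 3 each). Hypoxia response genes had 19 of 21 below 0 and a median of -0.07, with LOX, a collagen crosslinking enzyme, at -0.11 ± 0.05 and P4HA2, a collagen prolyl hydroxylase, at -0.12 ± 0.06 (SE). CDK inhibitors and p53 targets had 17 of 21 below 0 and a median of -0.06, with the pro-apoptotic gene PMAIP1 at -0.20 ± 0.09 and the DNA repair gene DDB2 at -0.18 ± 0.09 (SE). The unfolded protein response had 19 of 22 below 0 and a median of -0.05, with the chaperone gene DNAJB9 at -0.15 ± 0.08 and the translocon gene SEC61B at 0.09 ± 0.06 (SE). NF-kappaB and inflammatory cytokine genes had 14 of 22 below 0 and a median of -0.05, and glycolysis genes 14 of 21 below 0 and a median of -0.03. Camera adjusted p-values were 0.000517 for extracellular matrix and for hypoxia, 0.00431 for CDK inhibitors and p53 targets, 0.00773 for the unfolded protein response, 0.0374 for NF-kappaB and 0.0417 for glycolysis, and the adjusted p with an estimated correlation was 0.767 for all 6. The fry test called 0 lists, with a smallest adjusted p of 0.899, and no member of any list was called adjusted over the list alone. Without control 2, camera called 3 lists. The calls of extracellular matrix and hypoxia held with any single library left out. That of CDK inhibitors and p53 targets was lost without control 2 (median -0.02) or higher dose 1 (-0.02), and that of the unfolded protein response without control 1, control 2 or higher dose 3 (-0.03 each). NF-kappaB genes lost theirs without control 1 (-0.06), control 2 (-0.01), higher dose 1 (-0.04) or higher dose 3 (-0.05), and glycolysis without control 1 (-0.01), control 2 (-0.04), higher dose 1 (-0.03) or higher dose 3 (-0.03).

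The 20 lists not called at the higher dose had medians from -0.03 (interferon response) to 0.05 (markers of fibroblasts and smooth muscle). Steroid hormone synthesis had a median of 0.04, granulosa cell markers -0.01, FOXO targets -0.02 and insulin and IGF signalling components -0.01. Granulosa cell markers, histones and heat shock chaperones had medians whose sign differed from that of their mean or test. For all 32 tested insulin and IGF signalling genes the 95% interval excluded a 1.5-fold change against control, at either dose.

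The doses were then compared with each other. SOCS3, an inhibitor of cytokine and insulin receptor signalling (chromosome 17, 78356778 to 78360077, hg38), was measured at 13.7 ± 2.11 CPM at the higher dose and 18.2 ± 1.45 CPM at the lower (SD, n = 3 each), a log2 fold change of -0.41 ± 0.10 (SE). In control, SOCS3 stood between the doses, at 15.3 ± 0.960 CPM (SD, n = 3). Its adjusted p was 0.846 over all genes (edgeR quasi-likelihood, Benjamini-Hochberg) and 0.0270 adjusted over the list alone, the 32 insulin and IGF signalling components. Values adjusted over a list alone were not corrected for the number of lists and comparisons examined. JUNB lay lower at the higher dose by a log2 fold change of -0.23 ± 0.06 (SE), with an adjusted p of 0.846 over all genes and 0.0292 adjusted over the list alone, the 27 immediate early genes. JUNB stood at 47.2 ± 1.52 CPM in control, 55.1 ± 1.73 at the lower dose and 47.2 ± 2.69 at the higher (SD, n = 3 each). The same lower dose libraries enter this comparison and that with control, so the 2 JUNB results are not independent. IRS2 (chromosome 13, 109752698 to 109786568, hg38) stood at 41.0 ± 2.72 against 48.7 ± 2.13 CPM (SD, n = 3 each), with a log2 fold change of -0.25 ± 0.07 (SE) and an adjusted p of 0.846. Its 95% interval was 0.757- to 0.938-fold, with an unadjusted p of 0.00326 (edgeR quasi-likelihood). The other 2 genes named by smallest p were NEURL1B, a ubiquitin ligase gene, at -0.19 ± 0.05 and INCENP, a chromosomal passenger protein, at -0.28 ± 0.07 (SE). Their control means also lay between those of the doses, at 92.6 ± 2.54 CPM for NEURL1B and 61.7 ± 2.01 CPM for INCENP (SD, n = 3 each).

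Between the doses the edgeR quasi-likelihood test called 0 genes higher and 0 lower, with 720 of 12665 (5.68%) at an unadjusted p under 0.05, and DESeq2 called 0 of 15981 with 487. Without lower dose 1 the edgeR test called 2 genes lower at the higher dose, NDRG1, a stress-responsive gene, and TRIM22, an interferon-induced gene, both named after their values were seen. The 95% interval lay within 1.5-fold for 87.8% of the tested genes and within 2-fold for 95.4%. Groups did not overlap for 1540 genes (12.2%), where chance gives 10%.

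Camera with a preset correlation called 11 lists between the doses, 2 upward and 9 downward at the higher dose, and with an estimated correlation the smallest adjusted p over the 30 lists was 0.568, so that each call was lost. All 27 interferon response genes lay below 0, with a median of -0.11 (camera adjusted p = 9.27e-09; adjusted p = 0.568 with an estimated correlation). The ATF4 targets had 23 of 26 below 0 and a median of -0.10, the NF-kappaB list 18 of 22 and -0.09, and CDK inhibitors and p53 targets 17 of 21 and -0.10. Mitosis had 24 of 26 below 0 and a median of -0.05 (camera adjusted p = 0.00436; adjusted p = 0.779 with an estimated correlation). Extracellular matrix (25 of 31), glycolysis (19 of 21), hypoxia (17 of 21) and immediate early genes (22 of 27) had medians of -0.06, -0.06, -0.05 and -0.05. Interferon response, ATF4 targets, mitosis and immediate early genes had been called upward at the lower dose against control. The same lower dose libraries enter both comparisons, so the calls of these lists in the 2 comparisons are not independent. Upward, cholesterol synthesis had 21 of 24 members above 0 and a median of 0.07, and fatty acid synthesis and desaturation 14 of 16 and 0.06. For the 9 called lists other than interferon response and mitosis, the adjusted p with an estimated correlation was 0.568. The fry test called 0 lists, with a smallest adjusted p of 0.672. Without lower dose 2, camera called 3 lists, interferon response, ATF4 targets and extracellular matrix, whose calls held with any single library left out. The medians of the others were then 0.03 for cholesterol synthesis, 0.04 for fatty acid synthesis, -0.03 for glycolysis, -0.05 for mitosis and for CDK inhibitors, -0.01 for hypoxia, and -0.04 for NF-kappaB and immediate early genes. Calls were also lost without lower dose 3 for glycolysis (-0.03), CDK inhibitors (-0.05) and hypoxia (-0.02), without higher dose 1 for CDK inhibitors (-0.04) and hypoxia (-0.05), and for mitosis without higher dose 2 (-0.03) or higher dose 3 (-0.00386). The 19 lists not called had medians from -0.15 (epithelial markers) to 0.08 (steroid hormone synthesis). Signs of median, mean or test differed for lipid breakdown, ribosome biogenesis, NRF2 targets, epithelial markers and markers of fibroblasts and smooth muscle.

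**Figure D2:**
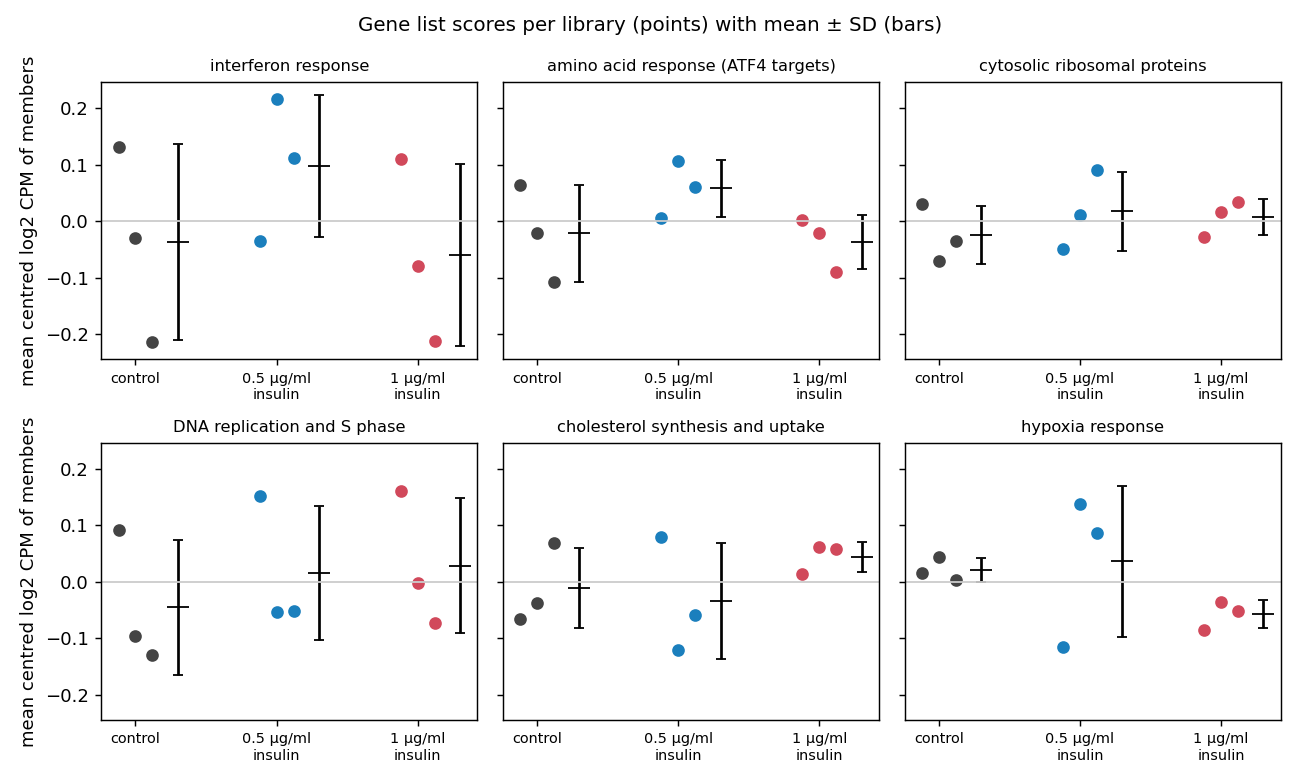
Scores of 6 gene lists per library: the vertical axis is the mean of the members' log2 CPM after each gene's mean was removed, points are libraries by group, and bars give the mean ± SD of 3 libraries. Interferon scores run from -0.21 to 0.13 among the control libraries alone, and the hypoxia score of lower dose 1 (-0.11) stands below the 0.14 and 0.09 of the other libraries of its dose.

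List scores were also tested with whole libraries as the unit. Over the 280 partitions of the 9 libraries, 0 of 30 lists had an exact permutation p under 0.05, the smallest was 0.0893 (granulosa cell markers), and the smallest after Benjamini-Hochberg adjustment over the lists was 0.897. A comparison of 3 libraries with 3 cannot give an exact two-sided p below 0.1.

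Fold changes at the doses were compared with each other across genes. The Pearson correlation of the log2 fold changes against control was 0.510 across 12665 genes, which are not independent replicates, and 64.1% had the same sign. Both comparisons share the control libraries, and unchanged groups simulated against such controls gave a correlation of 0.497 on average (0.466 to 0.529 over 20 simulations) and 66.7% with the same sign (66.3% to 67.9%). The observed share with the same sign lay below every simulation. The covariance was 0.0139, against 0.00999 (0.00900 to 0.0112) in the simulations, and 0.0104 when genes with a near-identical copy or without a GENCODE transcript were left out. The simulations drew genes independently and were not repeated on that smaller set. Whether 0.0104 exceeds what shared controls give there is not known. The number of genes called at both doses could only be 0, since neither comparison called a gene by the edgeR quasi-likelihood test (776 and 299 at an unadjusted p under 0.05) or by DESeq2 (573 and 173). The 3 control libraries cannot be divided into parts of at least 2, so part of any excess may come from the shared controls.

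Some genes varied many-fold between libraries of a group. U2AF1, a splicing factor gene on chromosome 21 (43092956 to 43107587, hg38), had counts of 23, 19 and 29 in control, 540, 19 and 26 at the lower dose and 196, 124 and 35 at the higher dose. U2AF1L5, its near-identical copy (6484623 to 6499261 on the same chromosome), had 343 counts in control 2 and between 8 and 29 in the other libraries. CBSL had 188 counts in control 3, 200 in higher dose 1 and 233 in higher dose 3, and between 1 and 32 in the others. These 3 genes were chosen after their values were seen.

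**Figure D3:**
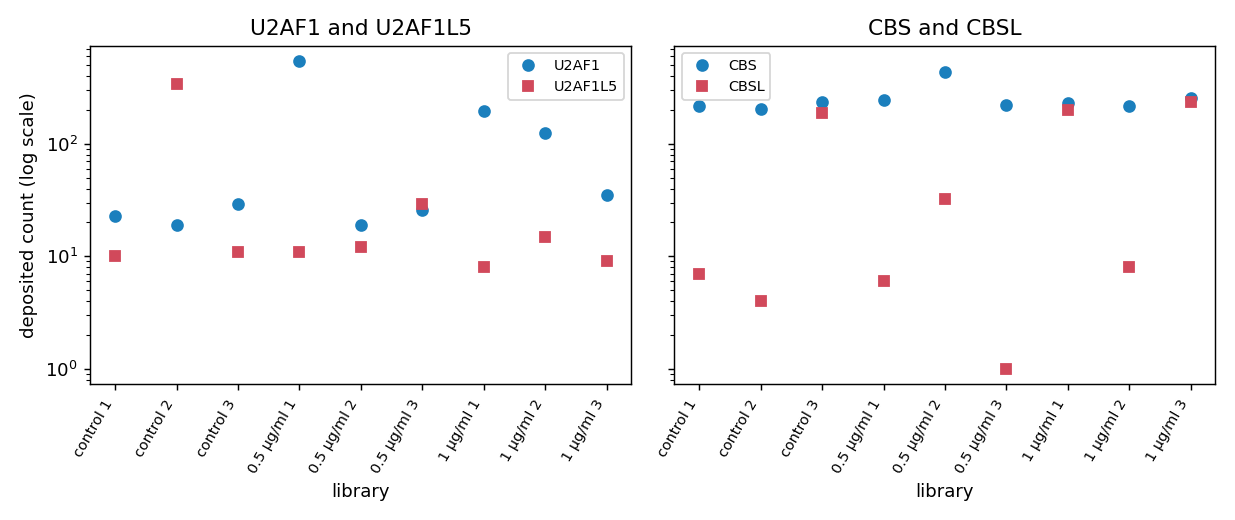
Deposited counts (vertical axis, log scale) of U2AF1 with U2AF1L5 and of CBS with CBSL in the 9 libraries (horizontal axis), a symbol for each gene. U2AF1 runs from 19 to 540 and CBSL from 1 to 233, with high and low libraries in more than a single group.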

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

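No TMM scaling, the exact permutation of list scores and the count over numberings of the libraries were chosen after seeing the data. For 156 of the alternative counts of genes the value stayed at 0, and 10 moved. Some of the 156 had to be 0: the minimum log2 fold change of 1 was applied to the main calls, which numbered 0. A count of genes called at both doses also cannot exceed that of either dose. DESeq2 called 1 gene in the 3-group test (LOC102724200). With the replicate block, 1 gene was higher (LOC107987373) and 1 lower (BOLA2B) at the lower dose than in control, and 5 differed among the 3 groups (BOLA2B, LOC102724200, LOC107987373, U2AF1L5 and VAMP7). Of these, BOLA2B and U2AF1L5 have near-identical copies, and their counts ran from 1 to 63 and from 8 to 343 over the libraries. Those of LOC102724200 ran from 3 to 46. Under the block, 975, 354 and 897 genes had an unadjusted p under 0.05 at the lower dose, the higher dose and between the doses. Without it the numbers were 776, 299 and 720. The smallest adjusted p with the block was 0.0348, 0.129 and 0.102 (edgeR quasi-likelihood, Benjamini-Hochberg). The labels do not say what the replicate numbers mark, and the numbers were not taken to pair the libraries. Same-numbered libraries of different groups correlated between -0.0117 and 0.161 in their deviations, and 1 of 9 pairs exceeded 0.1. Such low correlations over all genes do not exclude that same-numbered libraries share a state. As a hint from the data that they may share something, 4 of 9 libraries matched their own number best in both other groups, as many as in 2 of the 36 possible numberings, where the mean is 1. The first principal component also rose with the number in each group (-4.35, 2.57 and 15.4 in control, -12.3, -5.75 and -3.17 at the lower dose, -4.89, 1.36 and 11.1 at the higher). S phase scores, picked after they were seen, were highest in library 1 of control (0.0920), the lower dose (0.153) and the higher dose (0.161). The highest of the other libraries was higher dose 2, at -0.00156. Not every list followed the number in this way: the interferon score of lower dose 1 (-0.0355) was the lowest of its dose. Leaving out each library in turn gave 0 to 1 genes lower at the lower dose than in control (1 without control 2, LOC102724200), 0 to 2 lower at the higher dose than at the lower (2 without lower dose 1, NDRG1 and TRIM22), and 0 to 2 in the 3-group test (1 without control 2, 2 without lower dose 1, 1 without lower dose 3, 1 without higher dose 1). These few genes were chosen after their values were seen, and the cause was not tested.

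Lists called by camera numbered 1 to 12 at the lower dose when a library was left out (1 without control 3, 12 without lower dose 1, 2 without lower dose 2, against 6), 3 to 12 at the higher dose (3 without control 2, against 10) and 3 to 16 between the doses (3 without lower dose 2, against 11). With an estimated correlation and with fry the count was 0 in each comparison. Some directions turned when a library was left out, all in values near 0. At the lower dose the median log2 fold change ran from -0.0255 to 0.14 for S phase genes and from 0.000193 to 0.10 for mitosis genes, whose test pointed down at the lowest value. Ribosomal proteins at the lower dose had a median of -0.000354 without lower dose 3, and S phase genes at the higher dose -0.0137 without higher dose 1. Against control, the log2 fold change ran from -0.11 to 0.00298 for IGF1R and from -0.022 to 0.13 for IRS2 at the lower dose and from -0.0274 to 0.13 for INSR at the higher. Between the doses it ran from -0.14 to 0.00384 for INSR, from -0.0891 to 0.0242 for IGF1R and from -0.0254 to 0.0863 for IRS1. Over the alternatives, 963 values of named genes kept their direction and side of the threshold, as did 420 list tests, and 118 list calls were lost, besides 2 more at the lower dose, S phase without lower dose 1 and mitosis without control 3.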

Other observations

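The tests of the intervals, of near-identical copies, of sums of copies, of variance inflation and of S phase against hypoxia were chosen after the results they bear on, or values close to them, had been seen, as was the reading of which libraries the large splits hold together. Several gene lists moved together from library to library, whatever the dose. Over 435 pairs of the 30 lists, with shared members left out, 8 correlations of list scores across the 9 libraries had a Benjamini-Hochberg adjusted p under 0.05 by exact permutation. Interferon response and ATF4 targets had the largest of these (Pearson r = 0.955, exact permutation p = 0.000124, adjusted p = 0.0270; Spearman rho = 0.95, exact permutation p = 0.000353), with r = 0.912 without the 2 libraries farthest from the median and 0.956 after group means were removed. Interferon response also went with mitosis (r = 0.936, exact permutation p = 0.000372, adjusted p = 0.0405; rho = 0.867, exact permutation p = 0.00451), at 0.820 without the 2 farthest libraries and 0.938 after group means were removed.

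Metabolic lists paired in the same way. Cholesterol synthesis ran against glycolysis (Pearson r = -0.938, exact permutation p = 0.000314, adjusted p = 0.0405; Spearman rho = -0.933, exact permutation p = 0.000750), with r = -0.881 without the 2 libraries farthest from the median and -0.924 after group means were removed. CDK inhibitors and p53 targets went with hypoxia (r = 0.924, exact permutation p = 0.000650, adjusted p = 0.0456; rho = 0.917, exact permutation p = 0.00131), at 0.878 and 0.928 by the same 2 steps. The respiratory chain went with ribosomal proteins (r = 0.919, exact permutation p = 0.000733, adjusted p = 0.0456; rho = 0.95, exact permutation p = 0.000353), at 0.897 and 0.916. S phase genes went with the 9 tested epithelial markers, which include KRT7 at 21.6 ± 2.19 CPM (SD, n = 9) (r = 0.932, exact permutation p = 7.16e-05, adjusted p = 0.0270; rho = 0.933, exact permutation p = 0.000750), at 0.876 and 0.928. Both of these scores were highest in library 1 of each group, so their correlation also goes with the replicate number. The exact permutation took the 9 libraries as exchangeable and made no allowance for that. The other pairs were CDK inhibitors with autophagy (r = 0.892) and the TGF-beta with the YAP list (r = 0.822), both with an adjusted p of 0.0456 by exact permutation.

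A hypothesis that a common state of the culture, not the dose, sets S phase against hypoxia genes was tested on the same scores. After group means were removed their Pearson r was -0.637, which goes with it, but the relation itself did not pass: r = -0.595 (exact permutation p = 0.0934, adjusted p = 0.399 over the 435 pairs) and rho = -0.483 (exact permutation p = 0.194), with r = -0.475 without the 2 libraries farthest from the median. The question stays open.

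The lists called with a preset correlation may reflect members that vary together between libraries of a group. The 15 distinct called lists had a median variance inflation of 8.58 from within-group residuals, and all 30 tested lists one of 3.77, where the preset correlation allows a median of 1.22 and 1000 random lists of 26 genes had a median of 0.878. Of the 30 lists, 21 exceeded the 95th percentile of the random lists (2.06). An effect of insulin on these lists stays among the open explanations, since the loss of the calls with an estimated correlation does not show that the lists were equal between groups.

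The 6 libraries of a comparison can be split into 3 and 3 in 10 ways, the real one included in this and in the counts below, too few for a share under 0.05. For genes the real count was 0 in each comparison, which 10 of 10 splits reach whatever the data, so that number carries no information; the highest other split called 4 at the lower dose, 77 at the higher dose and 2 between the doses. For lists, 7 of 10 splits called as many as the real 6 at the lower dose (highest other 17), 3 of 10 as many as the real 10 at the higher dose (highest other 13) and 5 of 10 as many as the real 11 between the doses (highest other 16). In the 3-group test the real count was also 0, so all 100 splits drawn, the real one included, had to call as many, and this says nothing about chance; the highest other called 136.

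With all 9 libraries, no gene was called in any pairwise comparison by edgeR without the replicate block (776, 299 and 720 at an unadjusted p under 0.05) or by DESeq2 on unfiltered counts (573, 173 and 487). Leaving out control 2 or lower dose 1 gave the few calls named above. A spread too large to show 2-fold changes is argued against: in each comparison the 95% interval of at least 95.2% of the tested genes excluded a 2-fold change, while smaller changes stay open. Exchanging 2 libraries between groups raised the 3-group count to as much as 77 genes over the 27 exchanges, when control 3 and higher dose 1 changed places, so exchanged labels could account for part of the result and stay open. That count does not single out an exchange, since splits that are no exchange called up to 136 genes. Of the 7 splits with at least 50 genes, 6 held control 3 together with higher dose 2 and higher dose 3, as did 0 of the other 93. These libraries were picked after the same splits were seen, so the contrast describes the splits and tests nothing. A structure of the samples that the labels do not give stays open. A response to insulin too small for these data, or none at 72 h, stays open and was not tested.

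Genes that vary most between libraries of a group may share reads with near-identical copies. Among the 50 genes of largest within-group spread with at least 5 CPM, 46 had a GENCODE transcript and 8 of these (17.4%) had a near-identical copy, against 324 of 10371 other genes (3.12%), a ratio of 5.57 (Fisher's exact test, two-sided, p = 8.86e-05). The rule also counts a match to an overlapping transcript of another gene, as ACAT2 has. EIF3C and EIF3CL are each other's copy and are both among the 8, so the p-value treats linked genes as independent. The other genes were not matched for expression beyond the minimum of 5 CPM. Among the 50, CD99-2, FOXO3B, ASMTL-2 and LOC102724159 had no GENCODE transcript under their symbol, so whether they have a copy was not examined. CD99-2 had the largest spread of the 50, with a within-group SD of 1.98 in log2 CPM. Reads that only move between the copies of a pair, with their sum kept, are argued against: the sum of CBS and CBSL in CPM varied 2.36 times over the libraries, and that of U2AF1 and U2AF1L5 17.3 times. How reads with several matches were counted is not given in the sources used here, and 38 of the 46 genes had no such copy, so other causes stay open. No biological explanation was tested.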
